A study of Mus musculus with 12 samples.

How the data were processed

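Whole-transcriptome RNA sequencing was done on brain tissue of wild-type C57BL/6J mice, described by the submitters as injured cortex, from 12 libraries in 4 groups of 3. Per the labels' protocols, total RNA was isolated with a column kit, libraries were made with a strand-preserving kit, and paired reads were sequenced on an Illumina NovaSeq instrument. Per the submitters' processing notes, STAR 2.5.2a and featureCounts 1.4.3-p1 were used with the mm10 build. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so overlapping and antisense genes and close paralogs may share reads. The deposited values are raw read counts per gene, whole numbers with different totals in each library. Small even counts outnumbered odd ones, with 20514 values of 2 against 11222 values of 1, so the deposited counts appear to include both mates of a read pair and the number of fragments is then smaller.

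The table holds 53379 genes by versioned Ensembl identifier. Symbols came from a GENCODE M21 table, in which 53274 identifiers matched without version and 50604 with version, and positions come from the same release on GRCm38, for identifiers that matched with version. Replicates of each group were compared before use: every pair of libraries in a group differed far beyond sampling noise, so each library was counted once. Totals of 46362158 to 70754854 counts per library mean that counting error was small beside the spread between libraries, whose biological coefficient of variation was 0.289.

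All tests were fixed before the data were examined, unless stated. Genes were kept with filterByExpr over the 4 groups at its default minimum count of 10, leaving 19252 genes. Library sizes were scaled with TMM factors, and edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) was fitted to all 12 libraries with 4 group means, leaving 8 residual degrees of freedom for each gene. The 7 comparisons were injury within each diet, diet within each injury state, both effects averaged over the other factor, and their interaction. Benjamini-Hochberg adjustment ran over all 19252 genes with a threshold of 0.05. The standard errors given beside log2 fold changes were derived from the F statistic.

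Gene lists for cell types, brain regions, vascular, immune, lipid and energy pathways were fixed beforehand, 43 in number. One of them, hypothalamic neuropeptides, had fewer than 5 tested members and was not tested as a list. The other 42 were tested in each comparison with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 42 lists with a threshold of 0.05. Camera with an estimated correlation and fry were run beside it. Counts of members that pass adjusted over the list alone are given beside those over all genes. Some genes stand in more than 1 list. For the averaged comparisons the mean log2 CPM of each list (prior count 2) was also tested by an exact two-sided permutation of libraries within strata, whose smallest p is 0.005. For 3 libraries against 3 the smallest exact p is 0.1, so no such test is reported for the pairwise comparisons.

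Named genes followed a fixed rule, which left out predicted genes, pseudogenes and genes without a symbol. It took genes past the threshold, of which there were none in the main test, then for each list and comparison up to 2 members with the smallest p, then for each comparison the 10 genes with the smallest p and a mean of at least 1 CPM. Genes of both latter kinds are given as values only. Some genes that met this rule are not reported here. Markers of olfactory bulb were chosen after the principal components had been seen.

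The procedure was tested on simulated counts for the same 19252 genes, with 200 genes changed. The changed genes were drawn from those with a mean of at least 1 CPM. Genes varied independently, without shifts that many genes of a library share, so recovery in the real libraries may be lower. In a simulation of injury within the purified diet, edgeR recovered 51 of 100 genes changed 2-fold and 87 of 100 changed 4-fold and called 2 unchanged genes, while DESeq2 1.42.0 recovered 94 of the 4-fold genes and called 39 unchanged ones. In a simulation of the diet average, edgeR recovered 72 of 100 and 97 of 100 and called 6 unchanged genes, and DESeq2 called 56 unchanged genes.

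Alternatives planned beforehand were RLE and upper-quartile factors, DESeq2, limma-voom with and without sample quality weights or a correlation between libraries that share the first number of their name, other filters on low counts, fits on the compared groups only, the replicate number as a block, a surrogate variable (sva 3.50.0), a threshold of 0.10 and leaving out each library in turn. Other-tissue scores as covariates, leaving out the 2 libraries with transcripts of other regions, halved counts, and lists under other scalings or with fry on correlated libraries were added after the data had been seen. The choroid plexus and striatal lists are not judged with those covariates, which include their own scores. The choroid plexus score also sets the fish oil injured libraries largely apart. For comparisons with that group, lost or turned calls cannot tell adjacent tissue from the group itself. Calculations ran in R 4.3.3. No library was left out of the main tests.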

Results

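RNA was profiled from cortical tissue of wild-type C57BL/6J mice taken 6 months after repeated closed-head impacts milder than those of mild traumatic brain injury, or after sham handling. Mice received either a purified control diet throughout or a high-fat diet supplemented with fish oil in cycles. The 2 factors made 4 groups, purified sham, purified injured, fish oil sham and fish oil injured, with 3 libraries each and 12 in all. The diets differed in fat content as well as in fish oil, so the comparisons of diets do not separate them. The study title places the question in cerebrovascular metabolism and repair after brain injury. Total counts per library ran from 46362158 to 70754854, and 23207 to 24579 genes had counts in a library. The labels do not tie each library to a separate animal, so the p-values measure the spread between these libraries. All 12 libraries carried Y-linked transcripts at similar levels, such as Ddx3y at 91.4 to 133 CPM, and Xist at 0 to 0.197 CPM, the pattern of male mice.

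Transcripts of tissue next to the cortex differed widely between libraries of the same group. Ttr, which encodes transthyretin and is abundant in choroid plexus, stood at 2420, 2260 and 186 CPM in the fish oil injured libraries and at 434 CPM in purified sham replicate 3. In the other 8 libraries Ttr stood between 9.82 and 50.1 CPM. Cdhr1, Eomes and Doc2g, genes of olfactory bulb output neurons, reached 522, 91.1 and 31.4 CPM in purified injured replicate 3 and at most 25.9, 0.456 and 0.747 CPM elsewhere. Drd2, a dopamine receptor gene of striatal neurons, stood at 72.2 CPM in fish oil sham replicate 2, at 27.4 CPM in purified sham replicate 4 and at 0.331 to 10.5 CPM in the rest. Purified injured replicate 3 and fish oil sham replicate 2 are called the libraries of other regions here. These marker genes were chosen after their values were seen, except Ttr and Drd2, which belong to lists fixed beforehand. The leading principal components of log2 CPM held 23.4% and 18.4% of the variance, and the latter of them set purified injured replicate 3 apart.

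**Figure D1:**
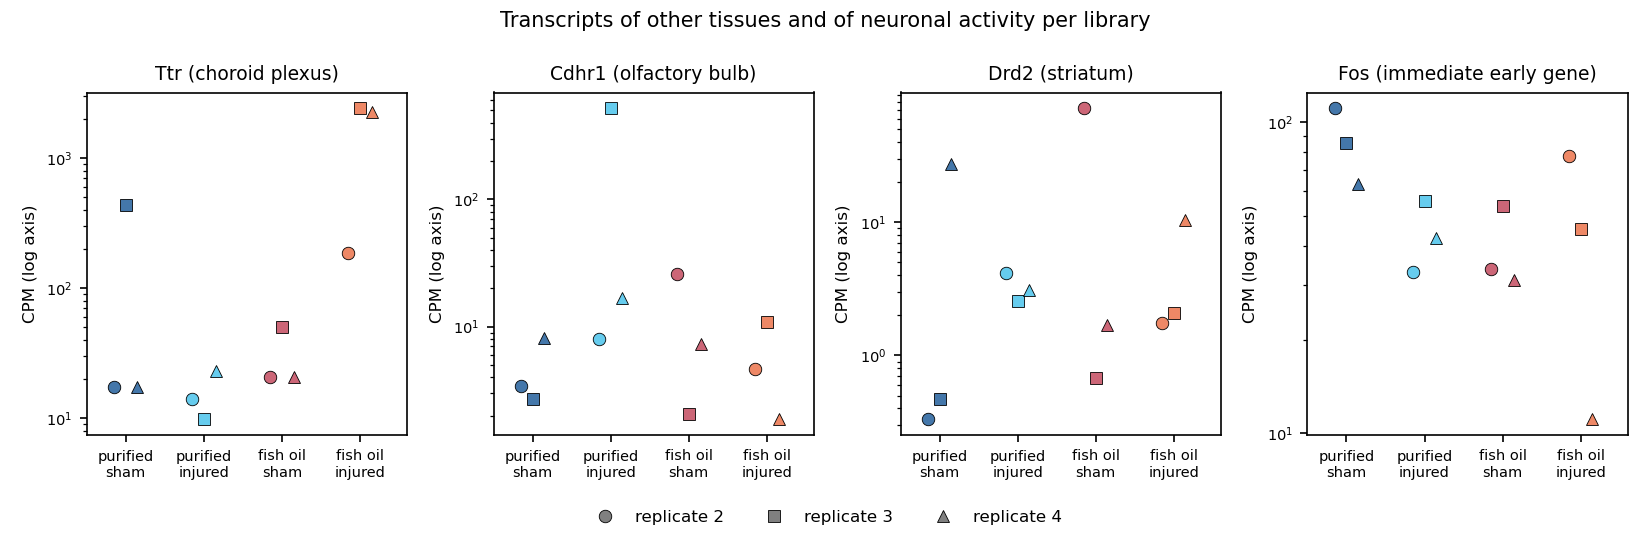
CPM on a log axis of Ttr, Cdhr1, Drd2 and Fos in each of the 12 libraries, 1 symbol per library and 3 libraries per group. Ttr reached 2420 CPM in a fish oil injured library, Cdhr1 522 CPM in purified injured replicate 3 and Drd2 72.2 CPM in fish oil sham replicate 2.

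In mice on the purified diet, injured libraries had lower values of the myelin genes and the immediate early genes and higher values of extracellular matrix and interferon response genes, and no single gene passed the test. The 16 genes of mature oligodendrocytes and myelin were all below 0, with a median log2 fold change of -0.66, among them Mog at -0.89 ± 0.47 (SE) and Mal at -0.90 ± 0.47. The myelin list passed the camera test (adjusted p = 4.0e-05, and adjusted p = 0.84 with an estimated correlation). The 18 immediate early genes, induced by neuronal activity, had a median of -0.73, with Egr1 at -0.99 ± 0.36 and the neurotrophin gene Bdnf at -0.59 ± 0.20 (adjusted p = 3.0e-05, and adjusted p = 0.84 with an estimated correlation). The extracellular matrix list had a median of 0.49 with 23 of 28 members above 0, including the collagen gene Col6a1 at 1.00 ± 0.34 (adjusted p = 0.00073, and adjusted p = 0.84 with an estimated correlation). Meningeal fibroblast genes moved with the matrix genes by library, in part because the lists share members. Among the purified injured libraries both scores were highest in replicate 4, at 0.98 and 0.46, and lowest in replicate 2, at -0.44 and -0.13. The interferon response list had a median of 0.21 with 18 of 22 above 0, including the antiviral genes Oasl2 at 0.89 ± 0.28 and Isg15 at 1.01 ± 0.36 (adjusted p = 0.0031, and adjusted p = 0.84 with an estimated correlation). Values given with 1 library left out or another setting are mean log2 fold changes of a list and log2 fold changes of a gene. Myelin genes (-0.32) lost the call without purified sham replicate 4, where Mog stood at -0.58 and Mal at -0.54. Extracellular matrix genes moved to 0.28 without purified injured replicate 4. Interferon response genes, with a mean of 0.307 over all libraries, lost the call without purified injured replicate 3 (0.22). Interferon response genes (0.15) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates.

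Among single genes, the smallest p-values after injury on the purified diet belonged to the sodium channel gene Scn7a (ENSMUSG00000034810.7), at 12.4 ± 2.03 CPM (SD, n = 3) in injured against 4.43 ± 0.573 in sham libraries, a log2 fold change of 1.49 ± 0.30 (SE). Mcub, a subunit of the mitochondrial calcium channel, had a log2 fold change of 2.96 ± 0.68. Lmo1 was at 1.32 ± 0.31, Usp46 at 0.58 ± 0.14 and Vwa5b1 at 0.92 ± 0.19. Tph2, the serotonin-making enzyme of neurons, was at -1.85 ± 0.42, the lipid droplet gene Plin4 at -1.48 ± 0.35, Sntb2 at -0.70 ± 0.14 and the mitochondrial tRNA gene mt-Tt at -1.44 ± 0.30. By edgeR 0 of 19252 genes passed in this comparison (lowest adjusted p = 0.763). In the purified diet 1251 genes had an unadjusted p under 0.05 where 963 are expected by chance, DESeq2 called 14 and limma-voom 0. Mcub moved to 1.80 without purified injured replicate 3.

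The camera test called 12 lists in purified-diet mice, 6 higher and 6 lower. Besides those above, the endothelial list had a median of -0.31 with 13 of 15 members below 0, including Ly6c1 at -0.72 ± 0.23, and the circadian clock list one of -0.11, with the core clock gene Arntl at -0.51 ± 0.15. Meningeal fibroblast genes had a median of 0.65, leukocyte genes 0.49, microglial genes 0.16, with the transcription factor gene Sall1 at 1.49 ± 0.52, lipogenesis genes 0.22, with malic enzyme gene Me1 at 0.34 ± 0.11. Nuclear-encoded oxidative phosphorylation genes had a median of -0.08 and choroid plexus genes -1.37. With an estimated correlation none of the 12 passed, the adjusted p being 0.84 or 0.85 for each of them. Whichever library was left out, 2 of the 12 lists passed, extracellular matrix genes and immediate early genes. Adjusted over the list alone, 0 members passed in each of these 12 lists, and 0 over all genes. The choroid plexus difference rests on purified sham replicate 3, where Ttr was high: without that library the mean log2 fold change was 0.09 in place of -1.30. Endothelial genes (-0.19) and nuclear oxidative phosphorylation genes (-0.011) lost the call without purified sham replicate 4, where homeostatic microglia genes stood at 0.48, leukocyte genes at 0.86 and lipogenesis genes at 0.25. Clock genes (-0.08), leukocyte genes (0.12), homeostatic microglia genes (0.19), meningeal fibroblast genes (0.10) and endothelial genes (-0.23) lost the call without purified injured replicate 4. Meningeal fibroblast genes (0.59), homeostatic microglia genes (0.14), leukocyte genes (0.38) and clock genes (-0.063) lost the call without purified sham replicate 2. Nuclear oxidative phosphorylation genes (-0.065) and choroid plexus genes (-1.04) lost the call without purified injured replicate 2, where leukocyte genes stood at 0.80. Homeostatic microglia genes (0.16), leukocyte genes (0.44) and lipogenesis genes (0.10) lost the call without purified sham replicate 3, where nuclear oxidative phosphorylation genes stood at -0.13. Lipogenesis genes (0.09) lost the call without purified injured replicate 3, where Sall1 stood at 0.28. Lipogenesis genes (0.073) and nuclear oxidative phosphorylation genes (-0.062) lost the call with other-tissue scores as covariates.

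In mice on the fish oil diet, injured libraries carried far more choroid plexus transcripts than sham libraries. All 15 members of that list were higher, with a median log2 fold change of 4.59. All 15 passed adjusted over the list alone, against 0 over all genes (camera adjusted p = 8.7e-46, and adjusted p = 0.065 with an estimated correlation). Coagulation factor V gene F5 (ENSMUSG00000026579.8) stood at 34.6 ± 24.4 CPM (SD, n = 3) against 1.12 ± 0.0393, with a log2 fold change of 4.94 ± 0.93 (SE). The folate receptor gene Folr1 was at 5.04 ± 1.06, the tight junction gene Cldn2 at 5.15 ± 1.10 and klotho, Kl, at 3.38 ± 0.73. The ependymal list had a median of 1.02 with all 10 members above 0, including Pifo at 2.54 ± 0.90 (adjusted p = 6.4e-06, and adjusted p = 0.59 with an estimated correlation). The cilia genes Drc7 and Dnah6 were at 2.47 ± 0.49 and 2.49 ± 0.56. Further genes with small p-values were Vwa5b1 at 1.29 ± 0.19, the lipopolysaccharide-binding protein gene Lbp at 2.88 ± 0.56, the desmosome gene Dsp at 2.74 ± 0.56 and the autotaxin gene Enpp2 at 2.19 ± 0.44.

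Genes of the unfolded protein and integrated stress response were also higher after injury on the fish oil diet, with a median log2 fold change of 0.20 and 17 of 18 members above 0. The chaperone gene Hspa5 was at 0.51 ± 0.15 and Manf at 0.38 ± 0.10, and 2 members passed adjusted over the list alone and 0 over all genes (camera adjusted p = 1.3e-05, and adjusted p = 0.32 with an estimated correlation). Heat shock genes had a median of 0.16 with all 12 above 0, and synapse genes one of 0.14, including the postsynaptic scaffold gene Homer1 at 0.88 ± 0.23 (adjusted p = 0.59 for both with an estimated correlation). The other lists called were oxidative phosphorylation at 0.07 and immediate early genes at 0.28 with Bdnf at 0.60 ± 0.20. Glucocorticoid response genes were at 0.18, ribosomal proteins at 0.05 and blood-brain barrier genes at 0.09, with the thyroid hormone transporter gene Slco1c1 at 0.57 ± 0.14 and the junction gene Ocln at 0.53 ± 0.18. Lower were pericyte and smooth muscle genes at -0.23 and interferon response genes at -0.21 with Rtp4 at -1.04 ± 0.28. Myelin genes were at -0.21 with Opalin at -0.58 ± 0.54 and striatal genes at -1.33. None of these last 9 lists passed with an estimated correlation, their adjusted p then running from 0.59 to 0.90. Adjusted over the list alone, 1 member of the blood-brain barrier list passed, Slco1c1, and 0 of the other 8. Barrier genes (0.12), immediate early genes (0.26), nuclear oxidative phosphorylation genes (0.073), ribosomal protein genes (-0.0055) and pericyte and smooth muscle genes (-0.26) lost the call without fish oil sham replicate 4, where myelin genes stood at -0.46. Glucocorticoid response genes (0.15), heat shock genes (0.17), immediate early genes (-0.061), striatal genes (-1.45), interferon response genes (-0.25) and pericyte and smooth muscle genes (-0.16) lost the call without fish oil injured replicate 2, where myelin genes stood at -0.61, nuclear oxidative phosphorylation genes at 0.18, ribosomal protein genes at 0.098, Homer1 at 0.51, Bdnf at 0.33 and Opalin at -1.09. Barrier genes (0.07), interferon response genes (-0.11), myelin genes (-0.14), synapse genes (0.11) and immediate early genes (0.15) lost the call without fish oil sham replicate 2, where striatal genes stood at 1.08 (past the threshold in the other direction) and ribosomal protein genes at 0.099. Glucocorticoid response genes (0.18), ribosomal protein genes (0.0023), immediate early genes (0.26), striatal genes (-1.47), myelin genes (0.079), interferon response genes (-0.15) and barrier genes (0.065) lost the call without fish oil injured replicate 3, where Opalin stood at -0.20. Barrier genes (0.078), nuclear oxidative phosphorylation genes (-0.001) and ribosomal protein genes (0.019) lost the call without fish oil injured replicate 4, where interferon response genes stood at -0.35 and immediate early genes at 0.61. Glucocorticoid response genes (0.17), ribosomal protein genes (0.034), myelin genes (-0.067) and interferon response genes (-0.23) lost the call without fish oil sham replicate 3, where immediate early genes stood at 0.61 and Opalin at -0.33. Barrier genes (turned to -0.018), interferon response genes (-0.18), synapse genes (turned to -0.014), nuclear oxidative phosphorylation genes (turned to -0.039), ribosomal protein genes (turned to -0.012) and heat shock genes (0.27) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates. Stress response genes (turned to -0.051) also lost the call with these covariates. The choroid plexus score ran from 0.883 to 3.7 in fish oil injured and from -1.12 to -0.926 in fish oil sham libraries. Calls lost or turned with these covariates therefore cannot tell adjacent tissue from the group itself. Myelin genes passed in the other direction with these covariates (1.19, adjusted p = 3.1e-24). Barrier genes (0.088), myelin genes (-0.25) and striatal genes (-1.63) lost the call with upper-quartile factors.

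For injury on the fish oil diet edgeR called 0 of 19252 genes (lowest adjusted p = 0.236, for Vwa5b1). On fish oil 670 genes had an unadjusted p under 0.05, fewer than the 963 expected by chance. DESeq2 called 37, of which 10 belonged to the choroid plexus list, and limma-voom called 1. Without fish oil injured replicate 2 edgeR called 7 genes, among them Lbp and Enpp2. Of the 14 lists called, 3 passed whichever library was left out, choroid plexus, ependymal and stress response genes.

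Between the diets in sham mice, genes of brain endothelial cells were lower on fish oil, together with clock and immediate early genes. All 15 endothelial markers were below 0. Their median log2 fold change was -0.63, and 9 of them passed adjusted over the list alone, against 0 over all genes (camera adjusted p = 5.2e-22, and adjusted p = 0.057 with an estimated correlation). Slco1a4 (ENSMUSG00000030237.14), an organic anion transporter of the blood-brain barrier, stood at 27.9 ± 2.16 CPM (SD, n = 3) on fish oil against 53.0 ± 7.41 on the purified diet, a log2 fold change of -0.93 ± 0.17 (SE). Ly6c1 was at -1.23 ± 0.23, Ly6a at -1.29 ± 0.28, the VEGF receptor gene Flt1 at -0.77 ± 0.16 and the angiopoietin receptor gene Tek at -0.79 ± 0.18. Outside the list, the endothelial adhesion receptor gene Adgrf5 was at -0.84 ± 0.13, the endothelial phosphatase gene Ptprb at -0.66 ± 0.12 and Slc2a1, the glucose transporter of the blood-brain barrier, at -0.47 ± 0.09. The barrier list had a median of -0.20, with Slco1c1 at -0.50 ± 0.14 and 3 of 15 members past adjusted over the list alone, and the angiogenesis list one of -0.15 with 2 of 21 past, 0 in both over all genes (camera adjusted p = 4.1e-05 and 0.013, and adjusted p = 0.14 and 0.25 with an estimated correlation). Angiogenesis genes (-0.06) lost the call without purified sham replicate 4, where barrier genes stood at -0.15. Angiogenesis genes lost the call without fish oil sham replicate 2 (-0.065) and fish oil sham replicate 3 (-0.12). Angiogenesis genes moved to -0.22 without fish oil sham replicate 4.

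All 17 clock genes were also lower in fish oil sham mice, with a median of -0.25. Per2 (ENSMUSG00000055866.9), a repressor in the clock loop, stood at 29.9 ± 2.77 CPM (SD, n = 3) against 52.4 ± 0.823, a log2 fold change of -0.81 ± 0.15 (SE), Bhlhe40 was at -0.75 ± 0.17 and Per1 at -0.54 ± 0.20. Of the 17 clock genes 2 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 2.7e-09, and adjusted p = 0.057 with an estimated correlation). The immediate early genes had a median of -0.90, with Egr3 at -0.92 ± 0.26 and Bdnf at -0.66 ± 0.20 (adjusted p = 3.3e-12, and adjusted p = 0.25 with an estimated correlation). Glucocorticoid response genes had a median of -0.09, with Plin4 at -1.56 ± 0.35, and 1 of 15 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 0.021, and adjusted p = 0.60 with an estimated correlation). Of the remaining genes with the smallest p-values, Ptgs2, which encodes cyclooxygenase 2, was at -1.44 ± 0.31 and the membrane progestin receptor gene Paqr5 at -1.17 ± 0.25. Glucocorticoid response genes lost the call without purified sham replicate 4 (-0.11) and fish oil sham replicate 3 (-0.20).

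Higher in fish oil sham mice were lists of lipid synthesis and glia. Cholesterol synthesis genes had a median of 0.18 with 22 of 24 above 0, including Dhcr7 at 0.40 ± 0.14 and Nsdhl at 0.41 ± 0.15. Lipogenesis genes had a median of 0.19 with 15 of 18 above 0, including the desaturase gene Scd2 at 0.40 ± 0.13 and the lipogenic regulator gene Srebf1 at 0.52 ± 0.19 (camera adjusted p = 1.9e-05 and 4.7e-05, and adjusted p = 0.60 and 0.25 with an estimated correlation). Oligodendrocyte precursor genes had a median of 0.32, with C1ql1 at 1.45 ± 0.49 (adjusted p = 0.25 with an estimated correlation). Homeostatic microglia genes were at 0.32, with P2ry12 at 0.34 ± 0.16. Fatty acid oxidation genes were at 0.13, with Cpt2 at 0.56 ± 0.22, ribosomal proteins at 0.10, oxidative phosphorylation at 0.07, disease-associated microglia at 0.18, extracellular matrix at 0.29. Meningeal fibroblasts were at 0.64, leukocytes at 0.55, striatal genes at 1.22 and choroid plexus genes at -1.45. For these last 10 lists the adjusted p was 0.60 with an estimated correlation. Extracellular matrix genes (0.24), leukocyte genes (0.35) and striatal genes (0.83) lost the call without purified sham replicate 2, where homeostatic microglia genes stood at 0.21. Extracellular matrix genes moved to 0.53, homeostatic microglia genes to 0.55, disease-associated microglia genes to 0.43, leukocyte genes to 0.83, striatal genes to 3.66, fatty acid oxidation genes to 0.28, nuclear oxidative phosphorylation genes to 0.17, ribosomal protein genes to 0.25 and P2ry12 to 0.52 without purified sham replicate 4. Extracellular matrix genes (0.21), meningeal fibroblast genes (0.28) and leukocyte genes (0.23) lost the call without fish oil sham replicate 4. Ribosomal protein genes (0.06), nuclear oxidative phosphorylation genes (0.047), fatty acid oxidation genes (0.12), striatal genes (0.84), leukocyte genes (0.41), disease-associated microglia genes (0.043) and choroid plexus genes (0.15) lost the call without purified sham replicate 3, where cholesterol synthesis genes stood at 0.14 and P2ry12 at 0.23. Disease-associated microglia genes (0.12) lost the call without fish oil sham replicate 2, where homeostatic microglia genes stood at 0.18, oligodendrocyte precursor genes at 0.25, striatal genes at -1.44 (past the threshold in the other direction), ribosomal protein genes at 0.078 and C1ql1 at 0.61. Nuclear oxidative phosphorylation genes lost the call without fish oil sham replicate 3 (0.073). Extracellular matrix genes (0.32) and disease-associated microglia genes (0.10) lost the call with other-tissue scores as covariates. Without fish oil sham replicate 2 the striatal value sets purified sham replicate 4, with Drd2 at 27.4 CPM, against libraries low in Drd2.

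Among sham mice edgeR called 0 of 19252 genes between the diets (lowest adjusted p = 0.686). In sham mice 710 genes had an unadjusted p under 0.05, DESeq2 called 17, of which 16 were lower on fish oil and 5 belonged to the endothelial list, and limma-voom called 0. Of 19 lists called, 8 passed whichever library was left out. These were endothelial, barrier, homeostatic microglia, oligodendrocyte precursor, immediate early, lipogenesis, cholesterol synthesis and clock genes.

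**Figure D2:**
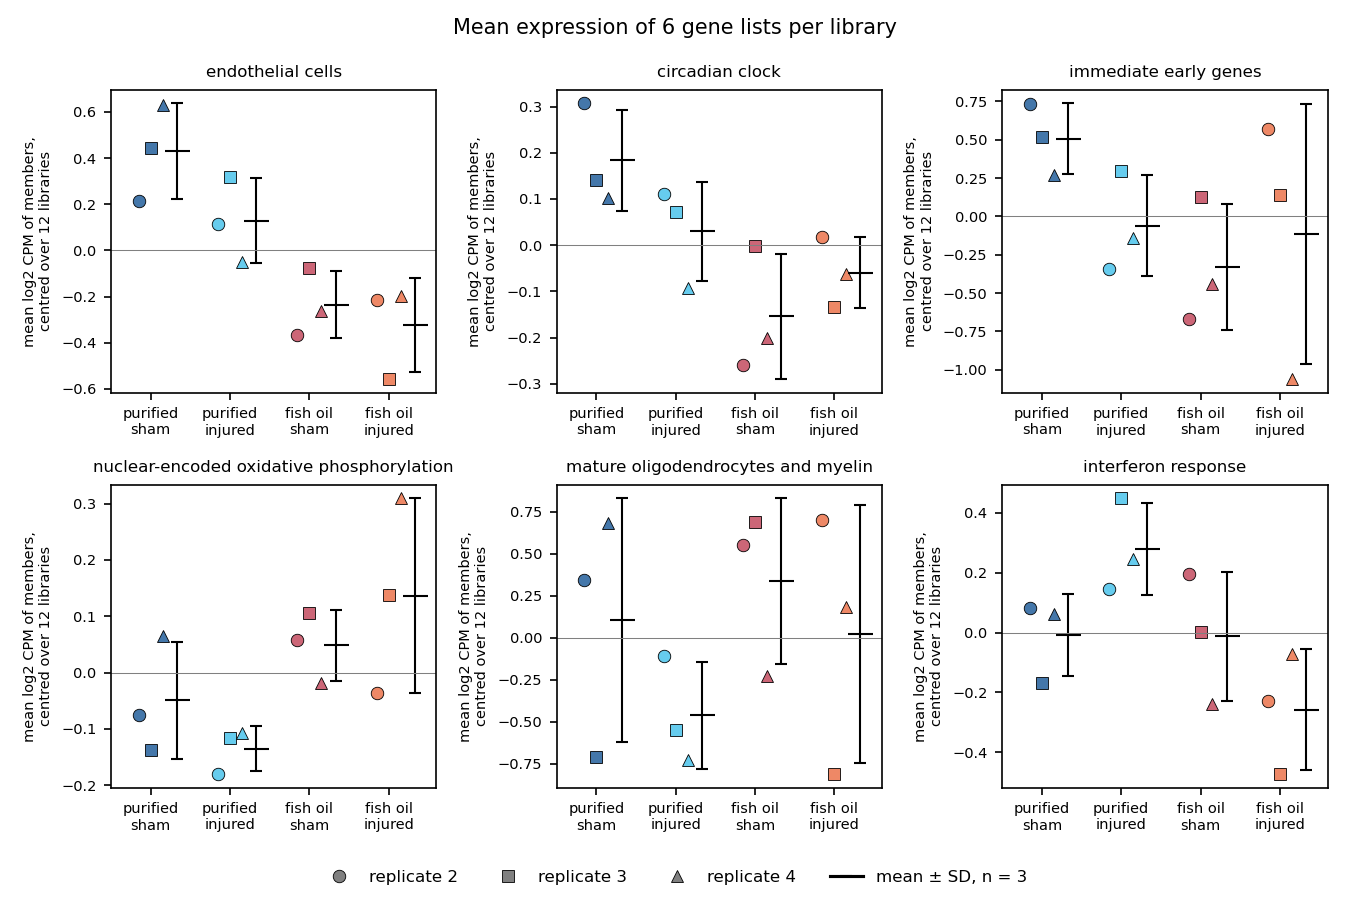
Mean log2 CPM of the members of 6 gene lists in each library, centred on the mean over the 12 libraries, with the mean ± SD of 3 libraries per group beside the points. The endothelial score was 0.43 ± 0.21 in purified sham and -0.24 ± 0.15 in fish oil sham libraries, and 0.13 ± 0.19 and -0.32 ± 0.20 in the injured groups.

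Between the diets in injured mice, endothelial genes were again lower on fish oil and interferon response genes were lower as well, while oxidative phosphorylation, ribosomal protein and choroid plexus genes were higher. All 15 endothelial markers were below 0, with a median log2 fold change of -0.47, including Slco1a4 at -0.72 ± 0.17 (SE), the adhesion molecule gene Pecam1 at -0.57 ± 0.18 and Flt1 at -0.50 ± 0.16. Of the 15 markers 6 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 1.4e-07, and adjusted p = 0.36 with an estimated correlation). The interferon response list had a median of -0.45 with 18 of 22 below 0, including Oasl2 (ENSMUSG00000029561.17) at 2.35 ± 0.812 CPM (SD, n = 3) against 5.96 ± 0.503, a log2 fold change of -1.34 ± 0.28, and Stat2 at -0.45 ± 0.14. Of the interferon genes 1 of 22 passed adjusted over the list alone (adjusted p = 5.2e-06, and adjusted p = 0.36 with an estimated correlation). Of the 80 nuclear genes of oxidative phosphorylation 78 were above 0, with a median of 0.24, and 84 of 87 ribosomal protein genes, with a median of 0.21, but none passed adjusted over the list alone or over all genes (camera adjusted p = 5.7e-16 and 2e-13, and adjusted p = 0.45 and 0.60 with an estimated correlation). Among them were the respiratory complex genes Ndufb11 at 0.53 ± 0.13 and Cox7b at 0.38 ± 0.12 and the ribosomal gene Rpl12 at 0.48 ± 0.15. Choroid plexus genes had a median of 4.10 with all 15 above 0 and 14 past adjusted over the list alone, including Kl at 4.10 ± 0.76 and F5 at 4.49 ± 0.91 (adjusted p = 4.6e-29, and adjusted p = 0.24 with an estimated correlation). Nuclear oxidative phosphorylation genes moved to 0.18 without fish oil injured replicate 4. Endothelial genes (-0.23) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates.

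The camera test called 15 lists between the diets in injured mice. Extracellular matrix genes had a median of -0.26, with the collagen genes Col6a1 at -1.51 ± 0.34 and Col4a1 at -0.64 ± 0.18 and 1 of 28 past adjusted over the list alone. Meningeal fibroblast and matrix scores moved together here too, at 1.03 and 0.39 in fish oil injured replicate 3 and at -0.90 and -0.55 in replicate 4. Angiogenesis genes had one of -0.28 with Dll4 at -0.99 ± 0.32, and pericyte and smooth muscle genes one of -0.37. Stress response genes were at 0.25, heat shock genes at 0.25 with Hsph1 at 0.37 ± 0.13, myelin genes at 0.62 with Mal at 0.85 ± 0.47. The mean of the stress response genes, to which the values with a library left out compare, was only 0.0694. Mitochondrially encoded genes were at 0.27, fatty acid oxidation at 0.14, ependymal genes at 0.73 and synapse genes at 0.11. With an estimated correlation the adjusted p of these 10 lists ran from 0.36 to 0.65. Whichever library was left out, 6 of all 15 passed, endothelial, angiogenesis, choroid plexus, interferon response, nuclear oxidative phosphorylation and ribosomal protein genes. Of the genes with the smallest p-values outside the lists, Tgfbr3l was at -1.66 ± 0.29 and the noncoding RNA gene Firre at -1.07 ± 0.20. Adamts10 was at -1.03 ± 0.20, the filamin gene Flna at -0.51 ± 0.10, Cab39l at 0.69 ± 0.14, and Drc7, Wdr86 and Enpp2 at 2.66 ± 0.49, 3.34 ± 0.63 and 2.37 ± 0.45. By edgeR 0 of 19252 genes passed (lowest adjusted p = 0.362). In injured mice 2063 had an unadjusted p under 0.05, 1314 of them lower on fish oil, DESeq2 called 186, of which 13 belonged to the choroid plexus list, and limma-voom called 0. Without purified injured replicate 4 edgeR called 61 genes, without fish oil injured replicate 2 it called 8, and without purified injured replicate 3, the library with olfactory bulb transcripts, it called 1. Ependymal genes (0.53), fatty acid oxidation genes (0.038), mitochondrially encoded genes (0.15), heat shock genes (0.13), stress response genes (-0.026) and pericyte and smooth muscle genes (-0.32) lost the call without purified injured replicate 2, where synapse genes stood at 0.25. Synapse genes (0.15), myelin genes (0.45), extracellular matrix genes (-0.10) and pericyte and smooth muscle genes (-0.28) lost the call without purified injured replicate 4, where heat shock genes stood at 0.45. Extracellular matrix genes (-0.27), myelin genes (0.20) and pericyte and smooth muscle genes (-0.23) lost the call without fish oil injured replicate 2, where Mal stood at 0.30. Fatty acid oxidation genes (0.10) and synapse genes (0.12) lost the call without fish oil injured replicate 3, where angiogenesis genes stood at -0.39, extracellular matrix genes at -0.61, myelin genes at 0.89 and stress response genes at 0.0094. Extracellular matrix genes (-0.15), ependymal genes (0.49), synapse genes (0.10), fatty acid oxidation genes (0.085) and mitochondrially encoded genes (0.16) lost the call without fish oil injured replicate 4. Synapse genes (0.053) lost the call without purified injured replicate 3, where fatty acid oxidation genes stood at 0.21, stress response genes at 0.22 and Hsph1 at 0.23. Angiogenesis genes (-0.25), synapse genes (turned to -0.14), fatty acid oxidation genes (0.068), mitochondrially encoded genes (0.078), heat shock genes (0.25) and stress response genes (turned to -0.03) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates.

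Averaged over both injury states, the diet difference was clearest in the endothelial list. All 15 markers were below 0. Their median log2 fold change was -0.56, and 14 passed adjusted over the list alone against 0 over all genes (camera adjusted p = 2.3e-22, and adjusted p = 0.12 with an estimated correlation). The exception, Cldn5, was at -0.27 ± 0.21 (SE) and is named after its value was seen. Slco1a4 was at -0.82 ± 0.12, Flt1 at -0.64 ± 0.11, Tek at -0.66 ± 0.13 and Abcb1a, the drug efflux pump of the barrier, at -0.56 ± 0.12. Adgrf5 (ENSMUSG00000056492.6), on chromosome 17 from 43360451 to 43459557 in GRCm38, stood at 25 ± 2.15 and 23.5 ± 3.38 CPM (SD, n = 3) in the fish oil groups. Adgrf5 stood at 44.6 ± 3.38 and 35.2 ± 3.76 CPM in the purified groups, a log2 fold change of -0.71 ± 0.09 and an adjusted p of 0.13. Ptprb was at -0.53 ± 0.08, Slc2a1 at -0.39 ± 0.07, the amino acid transporter gene Slc38a5 at -1.50 ± 0.27. Helz2 was at -0.79 ± 0.14, Zfp366 at -0.78 ± 0.16 and Per2 at -0.57 ± 0.11. The mean endothelial score differed by -0.56 between the diets, and in an exact two-sided permutation test of libraries within injury states p was 0.005, the smallest this design can give, and 0.21 after adjustment over the 42 lists. The fry test, which asks whether a list's genes move one way on balance, gave the endothelial list an adjusted p of 0.025 and passed no other list in any of the 7 comparisons. Cldn5 moved to -0.18 without purified sham replicate 4 and -0.16 without purified injured replicate 3.

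**Figure D3:**
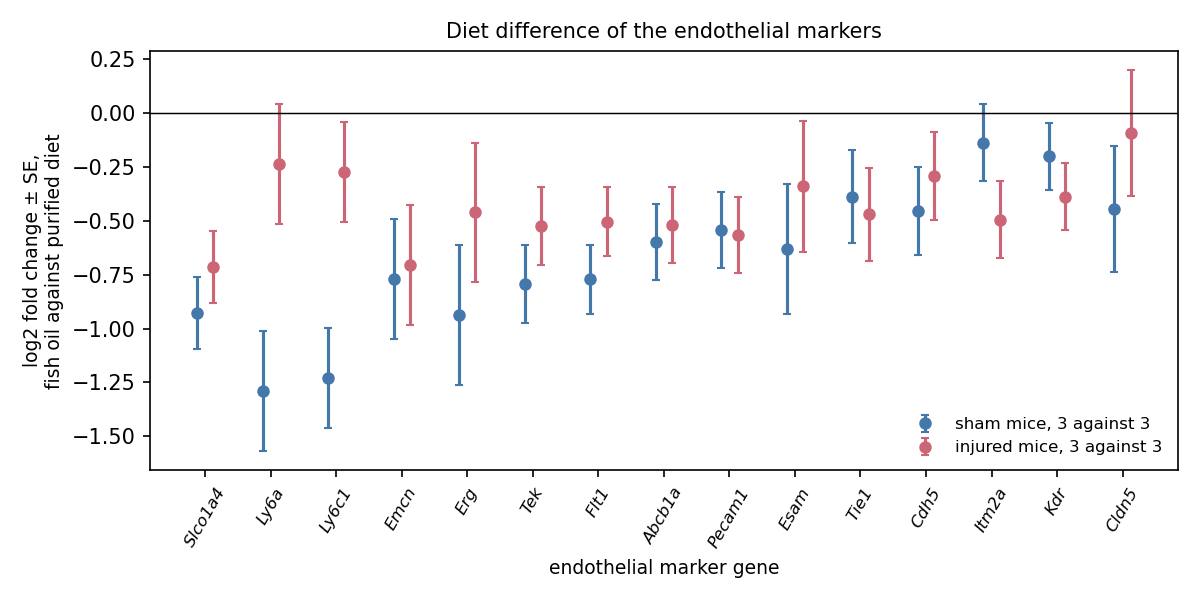
Log2 fold change ± SE of each of the 15 endothelial markers on fish oil against purified diet, in sham mice and in injured mice, 3 libraries against 3 in each. All points lie below 0, and 0 of the 15 genes passed over all genes in either comparison.

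Further lists called between the diets on average were nuclear oxidative phosphorylation, with a median of 0.15 and 77 of 80 members above 0, including Ndufb11 at 0.36 ± 0.09. Ribosomal proteins had a median of 0.15 with 83 of 87 above 0, including Rps29 at 0.35 ± 0.12 (camera adjusted p = 2.1e-15 for both, and adjusted p = 0.38 for both with an estimated correlation). The clock list had a median of -0.15 with 16 of 17 below 0, Bhlhe40 at -0.42 ± 0.12 and 3 past adjusted over the list alone. The angiogenesis list had one of -0.18, also with 3 past, 0 in both over all genes (adjusted p = 0.18 for both with an estimated correlation). Fatty acid oxidation genes were at 0.15, with Acaa2 at 0.40 ± 0.12 and Cpt2 at 0.45 ± 0.15. Lipogenesis genes were at 0.10, with Scd1 at 0.46 ± 0.16 and Scd2 at 0.28 ± 0.09, and cholesterol synthesis genes at 0.14, with Ebp at 0.27 ± 0.10 (adjusted p = 0.47, 0.38 and 0.48 with an estimated correlation). Interferon response genes were at -0.21, with Irf7 at -0.79 ± 0.23 and Oasl2 at -0.54 ± 0.20. Barrier genes were at -0.16 with 2 of 15 past adjusted over the list alone, pericyte and smooth muscle genes at -0.28, with Rgs5 at -0.44 ± 0.14, and immediate early genes at -0.38. Choroid plexus genes were at 1.70, also with 2 of 15 past, myelin at 0.41, oligodendrocyte precursors at 0.23. The choroid plexus value averages opposite differences, with means of -1.24 in sham and 4.26 in injured mice. Homeostatic microglia were at 0.17, disease-associated microglia at 0.13, astrocytes at 0.09, striatal genes at 0.81. Heat shock genes were at 0.14, stress response at 0.11, mitochondrially encoded genes at 0.15 and oxidative stress defence at 0.08. Across these last 15 lists the adjusted p ran from 0.27 to 0.65 with an estimated correlation. With any library left out, 13 of the 23 lists passed, endothelial, barrier, angiogenesis, choroid plexus, interferon response and clock genes among them. The others were oligodendrocyte precursor, immediate early, fatty acid oxidation, lipogenesis, cholesterol synthesis, nuclear oxidative phosphorylation and ribosomal protein genes. For the diet average edgeR called 0 of 19252 genes (lowest adjusted p = 0.13). On average 1704 had an unadjusted p under 0.05, 1174 of them lower on fish oil, DESeq2 called 99, 91 of them lower and 8 of them in the endothelial list. For the same average limma-voom called 0. Without purified injured replicate 4 edgeR called 7 genes, Adgrf5 and Slco1a4 among them. Myelin genes (0.19), heat shock genes (0.09) and pericyte and smooth muscle genes (-0.17) lost the call without fish oil injured replicate 2, where immediate early genes stood at -0.53. Oxidative stress defence genes (0.06), mitochondrially encoded genes (0.075), striatal genes (0.56), disease-associated microglia genes (0.013) and astrocyte genes (0.12) lost the call without purified sham replicate 3, where myelin genes stood at 0.22. Astrocyte genes (0.078), disease-associated microglia genes (0.013), mitochondrially encoded genes (0.071), heat shock genes (0.065), stress response genes (-0.0058) and oxidative stress defence genes (0.037) lost the call without purified injured replicate 2. Astrocyte genes (0.12), homeostatic microglia genes (0.064) and disease-associated microglia genes (0.059) lost the call without fish oil injured replicate 3, where stress response genes stood at 0.0084 and oxidative stress defence genes at 0.043. Mitochondrially encoded genes (0.09) and striatal genes (0.55) lost the call without purified sham replicate 2, where homeostatic microglia genes stood at 0.081. Heat shock genes (0.097) lost the call without purified sham replicate 4, where homeostatic microglia genes stood at 0.25, disease-associated microglia genes at 0.20, striatal genes at 1.97, mitochondrially encoded genes at 0.21 and stress response genes at 0.021. Oxidative stress defence genes (0.027), mitochondrially encoded genes (0.058), striatal genes (-0.57), disease-associated microglia genes (0.049) and homeostatic microglia genes (0.072) lost the call without fish oil sham replicate 2. Striatal genes (0.68) lost the call without purified injured replicate 3, where disease-associated microglia genes stood at 0.18, cholesterol synthesis genes at 0.072 and stress response genes at 0.12. Striatal genes (0.86) lost the call without purified injured replicate 4, where heat shock genes stood at 0.22 and oxidative stress defence genes at 0.10. Striatal genes (0.53) and mitochondrially encoded genes (0.075) lost the call without fish oil injured replicate 4, where immediate early genes stood at -0.19. Astrocyte genes lost the call without fish oil sham replicate 4 (0.13). Stress response genes, with a mean of 0.0377 over all libraries, moved to 0.019 without fish oil sham replicate 3. Astrocyte genes (0.14), homeostatic microglia genes (turned to -0.024), disease-associated microglia genes (0.13), immediate early genes (turned to 0.071), mitochondrially encoded genes (turned to -0.0062) and stress response genes (0.002) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates. Oxidative stress defence genes (turned to -0.01) also lost the call with these covariates. Homeostatic microglia genes (0.078), striatal genes (turned to -0.67), mitochondrially encoded genes (0.064) and oxidative stress defence genes (0.029) lost the call without both libraries of other regions.

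Averaged over both diets, Vwa5b1 (ENSMUSG00000028753.12), a von Willebrand factor A domain gene on chromosome 4 from 138565360 to 138635884 in GRCm38, came closest to the threshold for injury. It stood at 7.58 ± 1.28 and 10.6 ± 1.57 CPM (SD, n = 3) in injured mice on the purified and fish oil diets and at 4.00 ± 0.645 and 4.34 ± 0.391 CPM in their sham groups. This was a log2 fold change of 1.11 ± 0.14 (SE), with an edgeR adjusted p of 0.0716. Dsp was at 2.12 ± 0.39, Scn7a at 0.94 ± 0.21, the Wnt antagonist gene Sfrp1 at 0.61 ± 0.14, the GABA receptor gene Gabra3 at 0.31 ± 0.07. Plagl1 was at 0.51 ± 0.12, Nol4 at 0.35 ± 0.09, Trank1 at -0.39 ± 0.09, Zkscan6 at -0.29 ± 0.07 and the complement regulator gene Cd46 at -0.52 ± 0.13. The camera test called 6 lists: myelin genes with a median of -0.46 and all 16 below 0, including Opalin at -0.78 ± 0.39, endothelial genes with -0.23, including Pecam1 at -0.32 ± 0.12. Further lists were pericyte and smooth muscle genes with -0.24, choroid plexus genes with 1.32, including the water channel gene Aqp1 at 4.08 ± 1.09, ependymal genes with 0.21, and stress response genes at 0.06, including Hspa5 at 0.36 ± 0.10 and Pdia4 at 0.29 ± 0.09. All 6 had an adjusted p of 0.91 with an estimated correlation, and adjusted over the list alone 1 member passed among the choroid plexus genes, Aqp1, and 0 in the other 5. Passing with any library left out were 3 of the 6, endothelial genes, choroid plexus genes and myelin genes. The choroid plexus value averages opposite differences, with means of -1.3 on the purified diet and 4.19 on fish oil. The myelin score ranged from -0.71 to 0.68 within purified sham and from -0.81 to 0.70 within fish oil injured libraries. In the exact permutation test of list scores for injury, endothelial, choroid plexus and myelin genes had p = 0.105, 0.22 and 0.225, each 0.942 after adjustment. By edgeR 0 of 19252 genes passed, 694 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 2, both with Vwa5b1 among them, as did edgeR with no filter on low counts, where its adjusted p was 0.0235. Ependymal genes (0.20) and pericyte and smooth muscle genes (-0.099) lost the call without purified sham replicate 4, where myelin genes stood at -0.28. Pericyte and smooth muscle genes (-0.12) lost the call without purified injured replicate 3, where stress response genes stood at 0.066 and Aqp1 at 2.07. Stress response genes (0.14) and pericyte and smooth muscle genes (-0.14) lost the call without fish oil sham replicate 2. Ependymal genes (0.27) and pericyte and smooth muscle genes (-0.15) lost the call without fish oil sham replicate 4. Ependymal genes (0.24) and pericyte and smooth muscle genes (-0.17) lost the call without fish oil injured replicate 4. Ependymal genes (0.23) and stress response genes (0.13) lost the call without purified injured replicate 4. Pericyte and smooth muscle genes lost the call without fish oil injured replicate 2 (-0.10). Ependymal genes moved to 0.90 without purified sham replicate 2. Ependymal genes lost the call without purified sham replicate 3 (0.14). Myelin genes moved to -0.28 without fish oil injured replicate 3. Myelin genes (turned to 0.13), stress response genes (turned to -0.019) and pericyte and smooth muscle genes (-0.18) lost the call with other-tissue scores as covariates. Ependymal genes (0.37), stress response genes (0.062) and pericyte and smooth muscle genes (-0.10) lost the call without both libraries of other regions.

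Whether injury acted differently under the diets was tested as the interaction of diet and injury. The choroid plexus list had the largest difference, with a median of 4.71 log2 units and 14 of 15 members past adjusted over the list alone, among them F5 at 6.43 ± 1.23 (SE), Folr1 at 7.14 ± 1.44. Slc4a5 was at 9.34 ± 1.92, Cldn2 at 7.17 ± 1.49, Ttr at 9.04 ± 1.90 and Kcne2 at 6.78 ± 1.44, and 0 over all genes (camera adjusted p = 7.6e-33, and adjusted p = 0.18 with an estimated correlation). Immediate early genes had a median difference of 0.97, with Bdnf at 1.20 ± 0.28 and Egr3 at 1.26 ± 0.36 and 2 past adjusted over the list alone. Interferon response genes had one of -0.51, with Oasl2 at -1.60 ± 0.40 and 1 past, and extracellular matrix genes one of -0.62, with Col6a1 at -1.44 ± 0.48 (adjusted p = 0.62 for the 3 lists with an estimated correlation). Of 16 lists called here, 6 passed with any library left out, extracellular matrix, choroid plexus, interferon response, immediate early, glucocorticoid response and clock genes. Plin4 (ENSMUSG00000002831.13) had the smallest p-value of the named genes: it stood at 2.35 ± 0.921 CPM (SD, n = 3) in injured against 6.53 ± 2.34 in sham mice on the purified diet. On fish oil Plin4 stood at 4.69 ± 0.874 against 2.21 ± 0.54, an interaction of 2.56 ± 0.49. Homer1 was at 1.37 ± 0.33, the mitochondrial gene mt-Nd3 at 1.23 ± 0.39, Bhlhe40 at 0.66 ± 0.24. Per2 was at 0.48 ± 0.22, Dnah6 at 3.63 ± 0.77, Enpp2 at 2.89 ± 0.62 and Sox12 at -1.07 ± 0.24. By edgeR 0 of 19252 genes passed (lowest adjusted p = 0.82). For the interaction 1108 had an unadjusted p under 0.05, DESeq2 called 21, of which 8 belonged to the choroid plexus list, and limma-voom called 0. Immediate early genes moved to 0.46 without fish oil injured replicate 2. Ttr moved to 5.87 without purified sham replicate 3. Interferon response genes (-0.32) lost the call with other-tissue scores as covariates.

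Across the 19252 genes, log2 fold changes of injury on the purified diet and on the fish oil diet had a Pearson correlation of -0.06 and a Spearman correlation of -0.08, and those of diet in sham and in injured mice 0.01 and 0.07. With 1 library left out the injury correlation ran from -0.22, without fish oil sham replicate 3, to 0.07, without fish oil sham replicate 2, and the diet correlation from -0.11, without fish oil injured replicate 3, to 0.17, without purified injured replicate 4, so neither kept its sign. These correlations are across genes, which are not independent replicates. With an unadjusted p under 0.05 in both diet comparisons there were 88 genes, where 76.1 are expected for independent lists. Of these 88 genes 68 had the same sign. In both injury comparisons there were 33 genes, where 43.5 are expected, and 15 of the 33 had the same sign.

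Of the 42 lists tested, 12 passed the camera test in none of the 7 comparisons. These were reactive astrocytes, inflammatory cytokines and NF-kB targets, TGF-beta signalling and wound repair, proliferation, tau, amyloid and neurofilament genes, PPAR targets, eicosanoid genes, glycolysis, red blood cells, and inhibitory, hippocampal and thalamic neurons. For injury averaged over diets their medians ran from -0.12 in hippocampal neurons to 0.19 in PPAR targets, with reactive astrocytes at 0.05 and tau, amyloid and neurofilament genes at -0.04. For diet averaged over injury states they ran from -0.09 in inhibitory neurons to 0.28 in hippocampal neurons, with PPAR targets at 0.10 and eicosanoid genes at 0.05.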

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

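These 16 lists are given again here because the camera test of the diet by injury interaction with its preset correlation passed them at an adjusted p under 0.05. The test of choroid plexus tissue in the dissected piece was written before its result was seen, and that of library scaling after the choroid plexus result was seen.

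Median interaction log2 differences above 0, meaning a more positive injury response on fish oil, were 4.71 for choroid plexus, 1.33 for ependymal cells and 0.968 for immediate early genes. They were 0.461 for cortical excitatory neurons, 0.245 for heat shock, 0.233 for the circadian clock and 0.229 for the glucocorticoid response. They were 0.201 for the unfolded protein and integrated stress response, 0.169 for nuclear-encoded oxidative phosphorylation and 0.162 for mitochondrially encoded proteins. Synapse genes stood at 0.154 and cytosolic ribosomal proteins at 0.117. Below 0 were meningeal fibroblasts at -0.852, extracellular matrix at -0.617, interferon response at -0.51 and homeostatic microglia at -0.257. With an estimated correlation none of these lists passed, with adjusted p = 0.18 for choroid plexus and from 0.62 to 0.75 for the others. The values that follow are means over list members with 1 library left out or another setting. Over all libraries the mean was 0.0636 for the stress response and 0.287 for mitochondrially encoded proteins, unlike their medians. Meningeal fibroblast genes (-0.61), ependymal genes (0.44) and homeostatic microglia genes (-0.25) lost the call without purified sham replicate 2, where stress response genes stood at 0.022 and clock genes at 0.15. Homeostatic microglia genes (-0.29) and meningeal fibroblast genes (-0.10) lost the call without purified injured replicate 4, where ribosomal protein genes stood at 0.15 and heat shock genes at 0.46. Meningeal fibroblast genes (-0.37), mitochondrially encoded genes (0.25) and ribosomal protein genes (0.037) lost the call without fish oil sham replicate 4. Homeostatic microglia genes (-0.22) and meningeal fibroblast genes (-0.52) lost the call without fish oil injured replicate 2, where ribosomal protein genes stood at 0.14. Ribosomal protein genes (0.039) lost the call without fish oil injured replicate 3, where meningeal fibroblast genes stood at -1.34 and stress response genes at 0.0019. Mitochondrially encoded genes (0.18), nuclear oxidative phosphorylation genes (0.076), cortical excitatory neuron genes (0.24) and meningeal fibroblast genes (-0.40) lost the call without fish oil injured replicate 4, where ribosomal protein genes stood at 0.051. Mitochondrially encoded genes (0.088) and ribosomal protein genes (-0.048) lost the call without purified sham replicate 4, where homeostatic microglia genes stood at -0.60, nuclear oxidative phosphorylation genes at 0.10 and glucocorticoid response genes at 0.25. Homeostatic microglia genes (-0.21) lost the call without fish oil sham replicate 2, where ribosomal protein genes stood at 0.14. Mitochondrially encoded genes (0.17), ribosomal protein genes (0.018), heat shock genes (0.14) and stress response genes (-0.04) lost the call without purified injured replicate 2, where cortical excitatory neuron genes stood at 0.75. Synapse genes (0.12) and cortical excitatory neuron genes (0.22) lost the call without purified injured replicate 3, where stress response genes stood at 0.21. Synapse genes (0.16) lost the call without purified sham replicate 3, where ribosomal protein genes stood at 0.16 and stress response genes at 0.039. Mitochondrially encoded genes lost the call without fish oil sham replicate 3 (0.19). Cortical excitatory neuron genes (0.24), synapse genes (turned to -0.15), nuclear oxidative phosphorylation genes (0.023), mitochondrially encoded genes (0.17), ribosomal protein genes (0.016) and heat shock genes (0.21) lost the call with choroid plexus, striatal and olfactory bulb scores as covariates. Stress response genes (turned to -0.064) also lost the call with these covariates. Cortical excitatory neuron genes (0.14), synapse genes (0.058) and heat shock genes (0.16) lost the call without both libraries of other regions.

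The choroid plexus difference in injured mice on fish oil was weighed against 2 explanations. If choroid plexus tissue was taken along in the dissected piece, its markers should keep a common ratio to purified sham replicate 3, the other library high in Ttr. In fish oil injured replicates 3 and 4 this log2 ratio averaged 2.39 over the 15 markers (1.95 to 3.06, SD 0.278). Any rise in choroid plexus cells would give this too, so it cannot tell. Replicate 2 was not in this test, and its choroid plexus score of 0.883 lay below the 1.31 of purified sham replicate 3. Library scaling would shift other genes as abundant as the markers, and the median log2 difference of 13300 such genes was 0.0118. TMM scaling sets most genes near 0 beforehand, so this median cannot tell whether the scaling was right. It shows only that the markers rose beside genes of like abundance that did not.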

How the results depend on the processing

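The endothelial list stayed below 0 and past the camera threshold whichever library was left out, with mean log2 differences of -0.765 to -0.558 for diet in sham mice, -0.522 to -0.344 in injured mice and -0.608 to -0.505 on average. With other-tissue covariates its call was lost for diet within injured (-0.225, adjusted p = 0.063). The correlations of effects across genes did not keep their sign, running from -0.221 to 0.0714 for injury and from -0.106 to 0.165 for diet with 1 library left out. Other-tissue covariates, leaving out the 2 libraries of other regions, and fry with a shared library number were chosen after the data had been seen. Libraries held at least 46362158 counts, and with all counts halved and rounded edgeR also called 0 genes in each comparison, with 1260 against 1251 at an unadjusted p under 0.05 for injury within the purified diet and 2059 against 2063 for diet within injured. At this number of libraries edgeR called 51 of 100 genes changed 2-fold and 87 of 100 changed 4-fold in simulated counts. These counts lacked shifts shared by many genes of a library, so the shares are not the power for the real libraries. Except where named, the cause was not tested.

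Genes past the threshold were 0 in every comparison by edgeR. DESeq2 called 14 for injury within the purified diet, 37 for injury within the fish oil diet, 17 for diet within sham, 186 for diet within injured, 3 for injury averaged over diets, 99 for diet averaged over injury states and 21 for the interaction. In simulated counts DESeq2 also called 39 and 56 unchanged genes. For injury within the fish oil diet limma-voom called 1, with sample quality weights 1 and with a shared library number 1. For injury averaged over diets these 3 settings called 2, 2 and 2, while having no low-count filter gave 1 and a threshold of 0.10 gave 1. For diet averaged over injury states, limma-voom with a shared library number called 2 and having no low-count filter gave 2. Without the 2 libraries of other regions diet within injured gave 1. Leaving out 1 library at a time gave 0 to 7 genes for injury within the fish oil diet, 0 to 61 for diet within injured and 0 to 7 for diet averaged over injury states, and 0 elsewhere. The replicate number as a block gave 0 genes everywhere, and a pairing of libraries by that number was not established. With this block the call was lost for striatal genes in injury within the fish oil diet (-1.25) and synapse genes in diet within injured (0.147).

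Lists past the threshold fell to 0 in each of the 7 comparisons with an estimated correlation, and by fry to 0 in 6 and 1 in diet averaged over injury states. Fry with a shared library number passed 2 for diet within sham, 2 for diet averaged over injury states and 0 in the other 5. That setting took a correlation of -0.256 between libraries sharing the first number of their name, replicates 3 and 4 of each group, and the labels do not say what the number marks. Other-tissue covariates gave 8 for injury within the fish oil diet, of which 4 were called before in the same direction, 1 in the other and 3 were new. They gave 10 for the interaction, of which 7 were called before and 3 were new, the endothelial list among these. Leaving out 1 library at a time gave 11 to 19 lists for injury within the purified diet, 9 to 14 for injury within the fish oil diet and 4 to 16 for injury averaged over diets.

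With other-tissue covariates, mean log2 differences turned for injury within the fish oil diet in barrier genes (-0.0183), myelin (1.19), striatal neurons (0.218), synapse (-0.014), oxidative phosphorylation (-0.0389), ribosomal proteins (-0.0117) and the stress response (-0.0514). They turned in diet within injured for synapse (-0.143) and the stress response (-0.0301), and in injury averaged over diets for choroid plexus (-0.0302), myelin (0.127) and the stress response (-0.0194). They turned in diet averaged over injury states for choroid plexus (-0.0079), homeostatic microglia (-0.024), immediate early genes (0.0715), mitochondrially encoded proteins (-0.00624) and oxidative stress defence (-0.0101), and in the interaction for synapse (-0.151) and the stress response (-0.0641). Single genes that turned were Folr1 (-0.331) and Kl (-0.228) for injury within the fish oil diet, Kl (-0.0695) for diet within injured, and Folr1 (-0.00902) and Ttr (-0.288) for the interaction. Others were Ttr (0.0116) for injury within the purified diet, Opalin for injury within the fish oil diet (1.18) and averaged over diets (0.00683), and Pecam1 (0.0208) for diet within injured. Of the lists that turned with other-tissue covariates, myelin for injury within the fish oil diet passed in the other direction (adjusted p = 3.1e-24) and none of the others passed. For choroid plexus and striatal genes the values follow from the setting, since their own scores were covariates, and say nothing about them. In comparisons with the fish oil injured group the choroid plexus covariate nearly follows that group. The turns of other lists there cannot be ascribed to adjacent tissue.

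Without the 2 libraries of other regions striatal genes turned for injury within the fish oil diet (1.08), diet within sham (-1.43) and diet averaged over injury states (-0.668), and in the former pair they passed in the other direction (adjusted p = 0.0023 and 0.0097). Purified sham replicate 4, with Drd2 at 27.4 CPM, stays in that setting while fish oil sham replicate 2 is out, so the turn for diet within sham sets it against libraries low in Drd2. With 1 library left out, choroid plexus means ran from -1.71 to 0.0855 for injury within the purified diet and from -1.63 to 0.153 for diet within sham. Striatal means ran from -2.14 to 1.08 for injury within the fish oil diet, from -1.44 to 3.66 for diet within sham and from -0.573 to 1.97 for diet averaged over injury states. For injury within the fish oil diet, myelin ran from -0.614 to 0.0793, immediate early genes from -0.0614 to 0.614, oxidative phosphorylation from -0.000996 to 0.179 and ribosomal proteins from -0.00553 to 0.0987. Ribosomal proteins ran from -0.0475 to 0.159 in the interaction. The stress response ran from -0.0259 to 0.224 for diet within injured, from -0.00582 to 0.12 for diet averaged over injury states and from -0.0401 to 0.208 in the interaction.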

Other observations

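Fos, an immediate early gene, varied widely within groups. It stood at 111, 85.9 and 63.4 CPM in the purified sham libraries and at 11.1 CPM in fish oil injured replicate 4, against 77.9 and 45.3 CPM in the other fish oil injured libraries. The growth hormone gene Gh stood at 16.7 CPM in purified sham replicate 2 and at most at 2.45 CPM elsewhere, and the myelin gene Mbp ran from 708 to 2210 CPM within purified sham. Gh, Fos and Mbp were chosen after their values were seen.

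The tests of the endothelial and clock patterns were chosen only after those results were seen, as were the splits for gene counts, while the splits for list counts were chosen before.

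Lower endothelial markers on fish oil were weighed against 3 explanations. Library scaling should shift other genes too, and 7030 other genes of the same abundance had a median diet log2 difference of 0.00991. TMM scaling sets most genes near 0 beforehand, so this median cannot tell whether the scaling was right. It shows only that the markers, with a median of -0.559, lay below genes of like abundance. The lowest median among 10000 random lists was -0.252, but their genes were drawn singly, not as lists that move together. Tissue of other regions was tested by adding 3 tissue scores as covariates, and the difference stayed at -0.47 (95% interval -0.91 to -0.0303), which argues against it for both injury states averaged. In injured mice alone the list then lost its call (mean -0.225, adjusted p = 0.063). If vessels of every type were fewer, pericyte and smooth muscle genes should fall as far, but the endothelial minus mural difference was -0.325 (-0.704 to 0.0544, exact permutation p = 0.095), which cannot tell. A hypothesis is that the fish oil diet, through its oil or its fat content, lowered endothelial content or transcript levels, and vessel counts could test it beside this value of -0.325.

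Lower clock genes in fish oil sham mice were weighed against 2 explanations. With another time of day at collection, genes that peak opposite to the period genes should rise, but their mean log2 difference was -0.141 (-0.427 to 0.144, 4 genes), which cannot tell. If only activity-induced transcripts fell, clock outputs outside that class should stay at 0, and their mean was -0.286 (-0.681 to 0.108, 6 genes), which cannot tell either.

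The libraries were also split into groups, the real grouping counted as 1 of the splits, only as whether chance can be excluded. All possible splits were used for the comparisons of 3 libraries with 3. For the averaged comparisons and the interaction 100 splits were used, drawn at random except for the real one. For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. Genes past the threshold numbered 0 in the real grouping of every comparison, which any split must reach, so the splits say nothing about gene counts. They gave at least as many in 10 of 10 splits of each, the highest other being 0 for injury within the purified diet, 1 for injury within the fish oil diet, 0 for diet within sham and 1 for diet within injured. Lists numbered 12 in the real grouping for injury within the purified diet (highest other 26, at least as many in 6 of 10), 14 for injury within the fish oil diet (15, 3 of 10), 19 for diet within sham (23, 3 of 10) and 15 for diet within injured (20, 2 of 10). For the averaged comparisons and the interaction, 0 genes were likewise reached in 100 of 100 splits by necessity, the highest other being 0 for injury, 20 for diet and 242 for the interaction. Lists numbered 6 for injury (highest other 27, at least as many in 92 of 100 splits), 23 for diet (26, 5 of 100) and 16 for the interaction (24, 34 of 100). Chance is therefore not excluded for the list counts of the averaged comparisons and the interaction, and random splits of these libraries passed a median of 10 to 13 lists.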
